A study of Mus musculus with 7 samples.

How the data were processed

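Total RNA from the brains of 7 male C57BL/6J mice of 21 weeks was measured on Illumina expression BeadArrays, on which each probe is a DNA sequence carried by beads and biotin-labelled cRNA bound to it gives the signal. The labels place 4 mice in the wild-type group and 3 in the group homozygous for the knockout, and they give each array a mouse of its own, so each array was taken as 1 biological replicate. The values used were the deposited normalized values, which are intensities on a linear scale. The authors' software was GenomeStudio 2011.1, per the submitters' processing notes. The background subtraction and the normalization between arrays are read from the values alone, since negative intensities occur and the quantiles of the 7 arrays are nearly equal, and the normalization method is not given in the sources used here. The median intensity of each array lay between 14.556 and 14.623 and the 75th percentile between 176.3 and 177.4. A second deposited table of bead signals was not used here, because the names of its 7 signal columns match no sample label. The plan had been to correct and normalize that table, with a filter on its detection p-values. The normalized intensities took its place, with an intensity floor in place of the detection filter.

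Intensities under 16 were set to 16 and log2 values were taken. The floor lies above the noise around 0, where the 90th percentile of the size of the negative values was 4.19. Of the 25697 probes on the array, 12833 lay above 16 on at least 3 arrays and were tested. Between 12566 and 12581 probes lay above 16 on each array. The platform annotation gave 1 gene symbol for 23978 probes, several symbols for 0 and none for 1719. No symbol needed updating through the RefSeq gene table of assembly GRCm38.p6, which was used for names and for which genes neighbour each other. The tested probes with a gene numbered 12096 and stood for 9079 genes. No array was a copy of another's values, since the largest share of identical values in a pair was 0.00389%. Such a check cannot show whether a pair shared its RNA.

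Each tested probe was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with the group as the only term. Two-sided p-values were adjusted by the Benjamini-Hochberg method over all tested probes, with a threshold of 0.05. Every difference is the knockout mean minus the wild-type mean on the floored log2 scale, which understates differences of probes near the floor. Where all arrays of a group lay at the floor, the fold is a lower bound. Single values were compared by a two-sided exact permutation test over the 35 splits of the 7 arrays into groups of 4 and 3, for which the smallest possible p is 0.0286. The 35 gene lists were tested with limma's camera at a preset correlation of 0.01 and adjusted over the lists. Each gene in a list was represented by its probe of highest mean signal. The score of a list on an array is the mean, over its measured genes, of the deviation from the gene's mean over the 7 arrays. Members of a list were also adjusted over the list alone. Figures were drawn with matplotlib 3.10.9.

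The groups, the test, the gene lists, most of the alternatives and the rule for named genes were set before the data were examined. The rule named all probes of Pde4dip, then up to 12 genes per direction past the threshold with complete separation of the groups. Where fewer passed, the genes with the smallest unadjusted p filled each direction to 10, and up to 2 members per direction were named for each list. The use of the normalized table, its floor and 8 further alternatives were chosen after the data had been seen.

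The test was tried on simulated arrays with the spread of each real probe, for the comparison of 4 wild-type with 3 knockout arrays over 12833 probes. Noise was drawn independently for each probe, without the differences between arrays that many real probes share. The rates below may therefore not hold for the real arrays. Over 10 runs with 200 changed probes each, 41.3% of log2 changes of 1 and 79.3% of log2 changes of 2 were called, with 7.5 false calls per run. Of the unchanged probes, 5.28% had an unadjusted p under 0.05. Over 9079 genes simulated with independent noise, a list lowered by 0.5 was called in 100% of 20 runs and 0 other lists were called. In the scan of 31 measured neighbouring genes, the fullest window held a median of 3 top genes with nothing planted and 11 with 11 planted genes.

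Alternatives covered the floor, the filter, the normalization, the variance model, array weights, a hidden factor, the replicate number as a block, left-out arrays, the set test and the choice of probe. Precision is limited by the number of arrays. The median standard error of a log2 difference was 0.21.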

Results

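Brain RNA of 4 wild-type male mice and of 3 males homozygous for a knockout of Duf1220 was compared on 7 arrays, 1 per mouse. The series title describes mice without this protein domain as hyperactive and less fertile, and the comparison asks which brain transcripts differ in their absence. In the mouse the domain is encoded by Pde4dip, whose product myomegalin binds a cAMP phosphodiesterase and sits at the centrosome and the Golgi apparatus. Of 25697 probes, 12833 lay above an intensity of 16 on at least 3 arrays. Across these probes, which are not independent replicates, wild-type array 2 had a mean correlation of 0.932 with the other arrays and wild-type array 3 one of 0.970. The same mean was 0.976 to 0.981 for the remaining 5 arrays, 2 wild-type and 3 knockout. Pair by pair, with wild-type arrays 2 and 3 left out, those 5 correlated at 0.988 to 0.993.

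**Figure D1:**
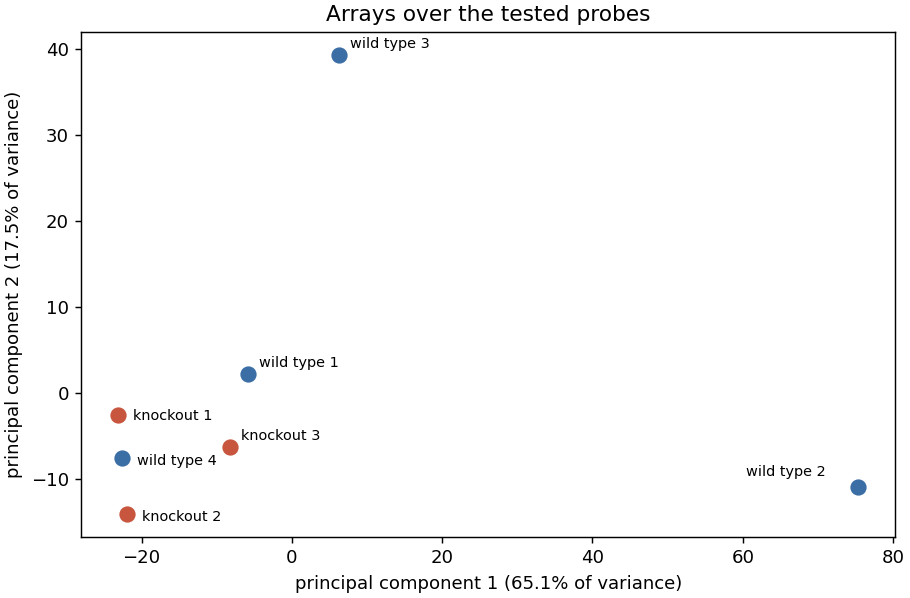
Position of the 7 arrays on the first 2 principal components of the floored log2 intensities of 12833 probes, with each point 1 array, wild type in blue and knockout in red. Wild-type array 2 lies at 75.3 on component 1, which holds 65.1% of the variance, and wild-type array 3 at 39.3 on component 2, which holds 17.5%, away from the other 5 arrays.

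Pde4dip transcript was lower in all 3 knockout brains at the brightest of its 3 probes and overlapped between the groups at the next. At probe ILMN_3064283 the intensity was 2271 ± 156 (SD, n = 4) in wild type and 1391 ± 139.6 (SD, n = 3) in knockout, a level 1.64-fold lower, or 38.9% below wild type. Probe ILMN_2751354, annotated to another transcript of the gene, read 494 ± 119 (SD, n = 4) in wild type and 489.8 ± 44.7 (SD, n = 3) in knockout. The first difference was -0.71 on the log2 scale (SE 0.15, 95% interval -1.04 to -0.38), and no wild-type array overlapped a knockout array (exact permutation p = 0.0286, the smallest that 35 splits allow). Over all probes it missed the threshold, with a limma adjusted p of 0.754. The second difference was 0.01 (SE 0.20, 95% interval -0.45 to 0.48, exact permutation p = 0.943), and its sign turned under some settings. Within each array the log2 ratio of the first probe to the second was 2.23 ± 0.25 (SD, n = 4) in wild type and 1.505 ± 0.069 (SD, n = 3) in knockout, a difference of -0.72 (exact permutation p = 0.0286). The third probe, ILMN_1215884, lay near the floor, above it on 2 of 4 wild-type and 1 of 3 knockout arrays. Its log2 levels were 4.39 ± 0.60 (SD, n = 4) and 4.04 ± 0.07 (SD, n = 3), with a difference of -0.35 (exact permutation p = 0.543), which was -0.053 without wild-type array 2 and -0.068 at a floor of 32. The position of the probes relative to the deleted part was not analysed here, and a probe outside that part does not check the genotype labels. With array weights the first difference was -0.68 at an adjusted p of 0.0437, and over its alternatives the adjusted p ranged from 0.0353 to 1.00. Within the wild-type group the weights rest mostly on array 1.

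**Figure D2:**
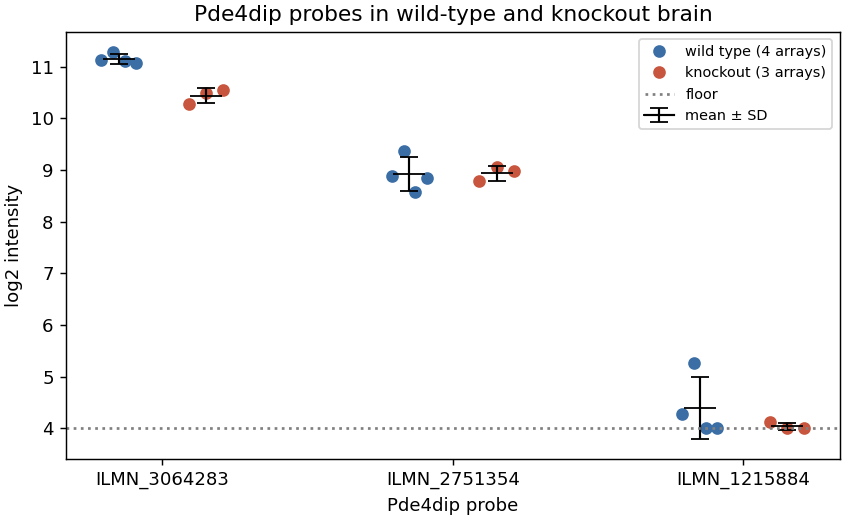
Log2 intensity of the 3 Pde4dip probes, with each point 1 array (4 wild type in blue, 3 knockout in red), the wide tick and bars the mean ± SD, and the dotted line the floor at 4 on the log2 scale. At ILMN_3064283 the knockout arrays lie between 10.27 and 10.55 and the wild-type arrays between 11.07 and 11.29, while at ILMN_2751354 the groups overlap.

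Across the whole array no probe passed the threshold with limma. Beside Pde4dip, the 6 genes with the smallest unadjusted p were Ctu1, a subunit of the enzyme that thiolates the wobble uridine of transfer RNA, S100a9, a calcium-binding protein abundant in neutrophils, and Rbbp5, a subunit of histone methyltransferase complexes, all higher in knockout, and Grwd1, a ribosome-assembly factor, Nosip, a nitric oxide synthase-interacting protein, and Folr1, a folate receptor of the choroid plexus, all lower. Ctu1 was 2.14-fold higher, at 33.3 ± 3.00 (SD, n = 4) in wild type and 71.9 ± 14.3 (SD, n = 3) in knockout. Grwd1 was 2.16-fold lower at probe ILMN_2815889, at 134 ± 30.2 (SD, n = 4) against 60.98 ± 1.68 (SD, n = 3). All 20 genes named by rank had an adjusted p of 0.754, and in all of them every knockout array lay beyond every wild-type array.

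Among the 10 genes with higher readings in knockout, the log2 difference was 1.29 (SE 0.25) for S100a9, 1.10 (SE 0.18) for Ctu1, 0.82 (SE 0.20) for the muscle ubiquitin ligase Fbxo32 and 0.80 (SE 0.19) for the ubiquitin ligase Traip. It was 0.87 (SE 0.22) for the nuclease Dnase1l2, 0.73 (SE 0.18) for the mitochondrial acyl-CoA dehydrogenase Acadl and 0.66 (SE 0.17) for the transcription factor subunit Gabpb1. The myeloid receptor Cd33 differed by 0.59 (SE 0.15) and the endothelial proteoglycan Esm1 by 0.55 (SE 0.13). Rbbp5 was at the floor on all 4 wild-type arrays at probe ILMN_2766338 and at least 1.61-fold higher in knockout. Several of these probes were dim, and the wild-type mean was 4.08 for Cd33, 4.02 for Esm1, 4.19 for Dnase1l2 and 4.22 for Traip, near the floor of 4. The sizes of dim genes rest on the floor, and at a floor of 32 the difference was 0.035 for Traip, -0.074 for Hes6 and -0.52 for Folr1.

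Among the 10 genes with lower readings, Folr1 differed by -1.35 (SE 0.30) and by -1.33 at its other probe. Spink8, a hippocampal protease inhibitor gene, differed by -1.17 (SE 0.30), Grwd1 by -1.11 (SE 0.20) and the microtubule-stabilising protein gene Map6 by -0.81 (SE 0.21). Nosip differed by -0.89 (SE 0.19), and its 2 other probes gave -0.91 and -0.64. For Ramp3, a receptor activity-modifying protein, the difference was -0.73 (SE 0.18), with -0.69 and -0.57 at 2 other probes. Slc22a17 differed by -0.66 (SE 0.16), the nucleolar protein gene Rrp1b by -0.64 (SE 0.16), Emd, which encodes the nuclear envelope protein emerin, by -0.63 (SE 0.15) and the neurogenic repressor Hes6 by -0.63 (SE 0.15). Ctu1, Cd33 and Nosip lie within 31 measured neighbouring genes of each other on chromosome 7. Probes of 1 gene disagreed in places. The other probe gave 0.16 for Grwd1, 0.15 for Map6, 0.06 for Slc22a17, -0.07 for Fbxo32 and -0.09 for Acadl, against the sign of the named probe. It gave only 0.02 for Rbbp5, 0.06 for Dnase1l2 and -0.16 (SE 0.17) for Hes6. For each of these genes the other probe had the higher wild-type mean. The log2 means were 10.97 against 5.67 for Slc22a17, 8.17 against 4.00 for Rbbp5 and 8.19 against 6.11 for Map6. They were 7.53 against 5.04 for Hes6 and 6.76 against 5.10 for Fbxo32. The gap was smaller for Acadl (5.39 against 4.45), Grwd1 (7.40 against 7.04) and Dnase1l2 (4.30 against 4.19).

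**Figure D3:**
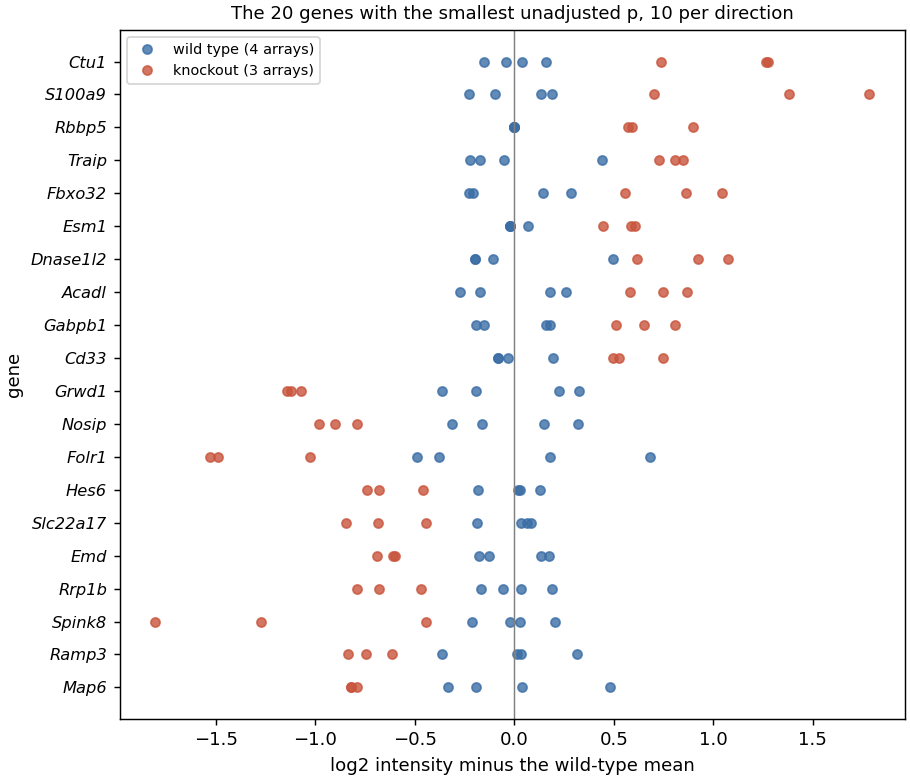
Log2 intensity minus the wild-type mean for the 20 genes named by rank, with each point 1 array (4 wild type in blue, 3 knockout in red). Every knockout point lies beyond every wild-type point of its gene, and the mean differences run from -1.35 for Folr1 to 1.29 for S100a9, although none passed the threshold.

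At an unadjusted p under 0.05, 539 probes differed, 284 higher and 255 lower in knockout, where 642 are expected by chance. The lowest adjusted p was 0.754, and 0 probes passed at 0.10. Complete separation of the groups held for 948 probes, 7.39% of those tested, where chance gives 5.71%. The unadjusted count was 1633 without wild-type array 4, and it lay between 163 and 289 without wild-type array 3 or without any 1 of the knockout arrays. With array weights, whose estimation stopped short of convergence and gave wild-type array 2 a weight of 0.104 and wild-type array 1 one of 6.71, 28 probes passed, 11 higher and 17 lower. With the first residual component as a covariate, 273 passed, 136 higher and 137 lower.

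Ribosomal protein transcripts were the only fixed list called at the main setting. All 20 measured members had lower means in knockout, with a median log2 difference of -0.25 (limma's camera, adjusted p = 6.80e-06). With an estimated correlation the list was not called, at a p of 0.170 and an adjusted p of 0.826. Rpl23 differed by -0.49 (SE 0.18) and Rps2 by -0.48 (SE 0.21), and 0 members passed over all probes or when adjusted over the list alone. Its score was 0.27 on wild-type array 2 and 0.39 on wild-type array 3, against -0.08 and -0.12 on wild-type arrays 1 and 4 and -0.10, -0.18 and -0.18 on the knockout arrays. Without wild-type arrays 2 and 3 the median difference was -0.05 with an adjusted p of 0.392, and with array weights it was -0.11 with an adjusted p of 0.152. Adjusted over the list alone, 2 members of all 35 lists passed, S100a9 in the blood list (adjusted p = 0.00733) and Folr1 in the choroid plexus list (adjusted p = 0.0277), and over all probes 0 passed. No correction was made over the 35 lists, so a few passes are expected by chance. The count of members passing over the list alone was 4 without wild-type array 2, 8 without wild-type array 4 and 4 without knockout array 1. The count of lists called was 3 without wild-type array 1 or without knockout array 2.

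Regional markers leaned in several directions without a call at the main setting, and some were called under other settings. The olfactory bulb and new neuron list had 14 of 16 measured members higher in knockout and a median of 0.33 (adjusted p = 0.0670), with the interneuron transcription factor gene Dlx1 at 0.73 (SE 0.31) and the neuropeptide gene Nmb at 0.44 (SE 0.20). Its score was 0.26 on wild-type array 1 and -0.08 on knockout array 2, against the direction of the list, -0.38 to -0.21 on the other wild-type arrays, and 0.32 and 0.31 on knockout arrays 1 and 3. Of its 2 lower members, Lhx5 differed by -0.02, and Tubb3, read at the floor on every knockout array, was above it on 3 wild-type arrays. The hypothalamic neuropeptide list had 13 of 15 higher and a median of 0.28 (adjusted p = 0.0838), with galanin (Gal) at 0.42 (SE 0.18) and vasopressin (Avp) at 1.26 (SE 0.60). The transcription factor gene Lhx1 of this list differed by -1.01 (SE 0.61) and Nkx2-1 by -0.06. On wild-type array 2 Lhx1 had a log2 intensity of 7.20, against 4.27 to 5.74 on the other wild-type arrays. Avp lay at the floor there, against 5.98 to 6.87. The hypothalamic score was -0.59 on wild-type array 2 and between -0.19 and 0.26 on the other arrays. In the hippocampal list 9 of 14 members were lower, with a median of -0.10 (adjusted p = 0.152), Spink8 at -1.17 and Fibcd1 at -0.49 (SE 0.23), and with Nts at 0.32 and Grp at 0.17. Its score was 0.09 ± 0.11 (SD, n = 4) in wild type, with 0.26 on wild-type array 2, and -0.12 ± 0.07 (SD, n = 3) in knockout (exact permutation p = 0.0286, adjusted over the 35 lists 0.733). The choroid plexus list had 10 of 17 lower and a median of -0.07 (adjusted p = 0.410), with Folr1 at -1.35, the chloride channel gene Clic6 at -0.30 (SE 0.13), Ecrg4 at 0.81 (SE 0.49) and Trpv4 at 0.27. The olfactory bulb list was called without wild-type array 1, without knockout array 2, with the mean over probes, with all probes of a gene and above the floor on all 7 arrays, and the hypothalamic list without wild-type array 1, with the mean over probes, with all probes of a gene and with the residual component. These calls are at the preset correlation, and with an estimated correlation at the main setting both lists had an adjusted p of 0.826. The hippocampal list was called above the floor on all 7 arrays, and the choroid plexus and pituitary lists without wild-type arrays 2 and 3, while with an estimated correlation at the main setting their adjusted p was 0.826, 0.826 and 0.924.

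Cortical, striatal, thalamic, cerebellar and brainstem markers were split about evenly. In the cerebral cortex list 8 of 15 members were higher and the median was 0.01 (adjusted p = 0.736), with Cux2 at 0.23 and Bcl11b at -1.11 (SE 0.53), and wild-type array 2 had a score of 0.50. The striatal list had 9 of 18 higher and a median of 0.02 (adjusted p = 0.736), with Ppp1r1b, which encodes DARPP-32, at -0.39 (SE 0.13) and the sodium channel subunit gene Scn4b at 0.45 (SE 0.27). In the thalamus and habenula list 10 of 18 were higher and the median was 0.07 (adjusted p = 0.736), with Ramp3 at -0.69 and Tnnt1 at -0.82 (SE 0.26), and with Zic4 at 0.51. The cerebellar list had 9 of 17 higher and a median of 0.04 (adjusted p = 0.909), with Svep1 at 0.61 (SE 0.18) and the Purkinje cell glutamate transporter gene Slc1a6 at -0.44 (SE 0.16). Brainstem and spinal markers had 5 of 10 higher and a median of -0.02 (adjusted p = 0.909), with Chat at 0.43 (SE 0.20) and the glycine receptor gene Glra1 at -1.16 (SE 0.41). Glra1 read 6.40 and 5.43 on the log2 scale on wild-type arrays 2 and 3, and 4.62 or less on all other arrays. The pituitary list had 4 measured members and a median of -0.64 (adjusted p = 0.766), with growth hormone (Gh) at -1.84 (SE 1.38), prolactin (Prl) at -1.46 (SE 1.10) and Dlk1 at 0.66.

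Lists tied to activity and reproduction were not called at the main setting, and the immediate early gene list was called without knockout array 2, while with an estimated correlation at the main setting its adjusted p was 0.826. Dopamine genes had 9 of 13 members higher and a median of 0.13 (adjusted p = 0.736), with Ppp1r1b at -0.39, Foxa1 at 0.93 (SE 0.28) and the dopamine transporter gene Slc6a3 at 0.30 (SE 0.23). Foxa1 lay near the floor in wild type, with a log2 mean of 4.06 and 2 of 4 arrays above the floor. On the knockout arrays it read 4.28 to 5.63. Serotonin and noradrenaline genes had 7 of 9 higher and a median of 0.29 (adjusted p = 0.456), with the transcription factor genes Gata3 at 0.48 (SE 0.20) and Gata2 at 0.39, the receptor gene Adra2c at -0.30 and a score of -0.41 on wild-type array 2. Neuropeptides and receptors of reproduction had 4 of 6 higher and a median of 0.30 (adjusted p = 0.736), with Gal and Avp as above, the neurokinin receptor gene Tacr3 at -0.22 and a score of -0.79 on wild-type array 2. Immediate early genes had 10 of 14 higher and a median of 0.23 (adjusted p = 0.410), with Arc at 1.02 (SE 0.52), Per1 at 0.69 (SE 0.32) and Egr1 at -0.19, and scores that ran from -0.39 to 0.48. On wild-type array 2 Arc had a log2 intensity of 6.90, against 8.28 to 9.37 on the other wild-type arrays. Per1 had 8.09 there, against 9.17 to 9.59. Circadian clock genes had 7 of 16 higher and a median of -0.08 (adjusted p = 0.766), with Per3 at 0.84 (SE 0.40) and Rora at -0.50. The log2 intensity of Per3 was 4.44 and 4.59 on wild-type arrays 2 and 3, against 5.74 to 6.29 on all other arrays. Glucocorticoid and heat-shock genes had 9 of 19 higher and a median of -0.02 (adjusted p = 0.766), with Hspa1a at 0.35 and Hspa8 at -0.32 (SE 0.16). Glutamatergic synapse genes had 9 of 13 higher and a median of 0.16 (adjusted p = 0.954), while the vesicular transporter gene Slc17a7 stood at -0.63 (SE 0.21), the scaffold gene Dlg4 at -0.52 (SE 0.20) and the receptor gene Gria4 at 0.96 (SE 0.44). Gria4 lay at the floor on wild-type array 2 and at 4.74 on wild-type array 3, against 5.62 to 6.22 on all other arrays. GABAergic genes had 12 of 17 higher and a median of 0.13 (adjusted p = 0.510), with Dlx1 at 0.73, Gabra6 at 0.73 and Gabrb1 at -0.70 (SE 0.32).

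No list of genes related to the targeted protein was called. Myomegalin partners and centrosome or Golgi microtubule genes had 8 of 19 members higher and a median of -0.02 (adjusted p = 0.766), with the Golgi matrix gene Golga2 at -0.57 (SE 0.19), the gamma-tubulin gene Tubg1 at -0.46 (SE 0.20), Nedd1 at 0.50 (SE 0.17) and the anchoring protein gene Akap9 at 0.34 (SE 0.16). Phosphodiesterase and cAMP genes had 15 of 22 higher and a median of 0.11 (adjusted p = 0.736), with Pde4d at 0.36 (SE 0.16) and Pde4a at -0.61 (SE 0.36). Microcephaly genes had 6 of 12 higher and a median of 0.01 (adjusted p = 0.982), with the condensin genes Ncapd3 at 0.82 (SE 0.32) and Ncaph at -0.36. Of 17 measured genes near Pde4dip on chromosome 3, 9 were higher and the median was 0.00411 (adjusted p = 0.954), with Acp6 at 0.54 (SE 0.21), Phgdh at -0.59 (SE 0.25) and Hsd3b2 at -0.65 (SE 0.28). Of 3 measured genes that differ between C57BL/6J and C57BL/6N, Entpd4 stood at -0.46 (SE 0.17), Ide at -0.29 and Snap29 at 0.05 (list median -0.29, adjusted p = 0.410). Wild-type array 2 carries the Ide value, with a log2 intensity of 8.84 against 7.29 to 7.42 on the other wild-type arrays and 7.37 to 7.50 in knockout, and it had a list score of 0.60.

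Markers of other cell types gave no call either. Astrocyte genes had 10 of 17 members lower and a median of -0.11 (adjusted p = 0.410), with Fgfr3 at -0.55 (SE 0.24) and S100b at 0.34. Oligodendrocyte genes had 9 of 16 lower and a median of -0.04 (adjusted p = 0.721), with transferrin (Trf) at -0.57 (SE 0.21) and Fa2h at 0.47. Microglial genes had 9 of 15 lower and a median of -0.03 (adjusted p = 0.736), with Aif1 at -0.57 (SE 0.24) and P2ry12 at 0.64. Interferon-response genes had 11 of 14 higher and a median of 0.13 (adjusted p = 0.736), with Stat2 at 0.75 (SE 0.44) and Rsad2 at -0.42. Stat2 had a log2 intensity of 4.63 on wild-type array 2, against 5.99 to 6.71 on the other wild-type arrays. Endothelial and pericyte genes had 12 of 18 higher and a median of 0.10 (adjusted p = 0.736), with Cdh5 at 0.39 (SE 0.16) and Acta2 at -0.39. Ependymal genes had 4 of 5 lower and a median of -0.19 (adjusted p = 0.721), with Tekt1 at -0.23 and Mia at 0.69 (SE 0.32). Meningeal and fibroblast genes had 13 of 19 higher and a median of 0.13 (adjusted p = 0.736), with Ogn at 1.48 (SE 0.67) and Slc22a6 at -0.48, and a score of -0.41 on wild-type array 2. Ogn read 4.12 and 4.54 on the log2 scale on wild-type arrays 2 and 3, against 6.61 to 7.11 on all other arrays. In the blood list 5 of 9 members were lower and the median was -0.04 (adjusted p = 0.982), with the neutrophil genes S100a9 at 1.29 and S100a8 at 0.88 (SE 0.30), the haem synthesis gene Alas2 at -1.07 (SE 0.50), and a score of 0.74 on wild-type array 2. Cell cycle genes had 6 of 11 higher and a median of 0.06 (adjusted p = 0.736), with Rrm1 at 0.30 and Cdc20 at -0.34. Oxidative phosphorylation genes had 13 of 27 higher and a median of -0.00215 (adjusted p = 0.736), with Ndufb7 at -0.57 (SE 0.21) and Ndufa1 at 0.50. Of the 7 measured genes of the X and Y list 3 were higher, with Eif2s3y at 0.91 (SE 0.36), Kdm5c at -0.37 and a median of -0.05 (adjusted p = 0.954). Eif2s3y read 6.37 and 6.49 on the log2 scale on wild-type arrays 2 and 3, against 7.42 to 7.99 on all other arrays. The sign of the median and the direction of camera differed for the cerebral cortex, striatum, thalamus, glutamatergic, microcephaly, Pde4dip neighbour and X and Y lists. The mean differed in sign from the median for the cerebral cortex, striatum, thalamus, circadian, glucocorticoid and X and Y lists.

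**Figure D4:**
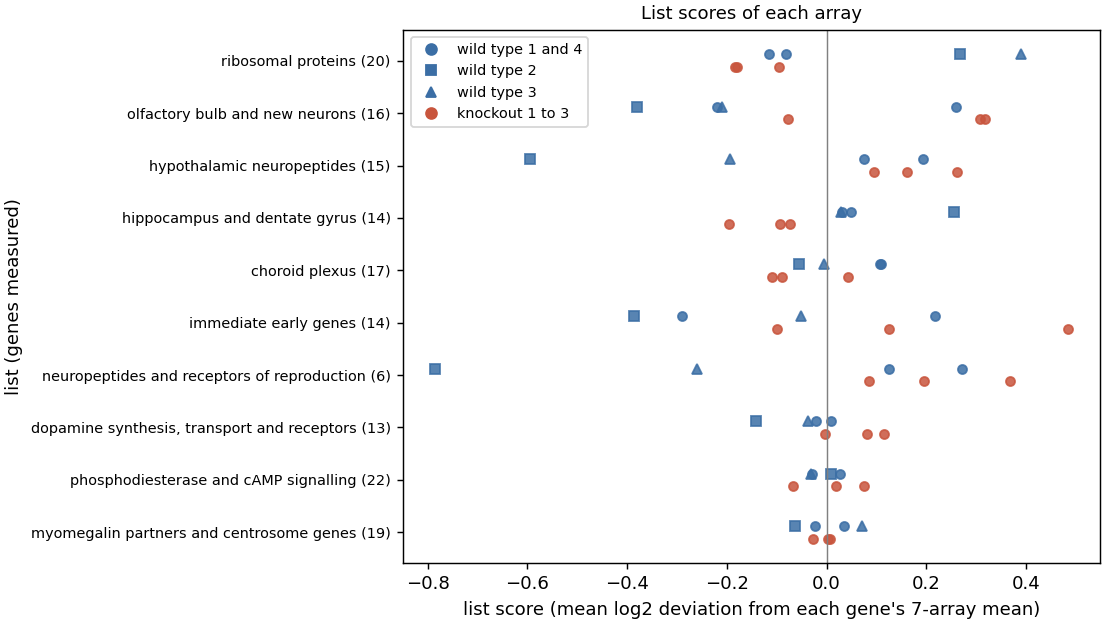
Score of 10 of the fixed lists on each array (mean log2 deviation of the measured genes from their mean over 7 arrays), with each point 1 array, wild type in blue and knockout in red. The ribosomal score of 0.27 on wild-type array 2 (square) and 0.39 on wild-type array 3 (triangle) stands above all other arrays, and the hypothalamic score of wild-type array 2 is -0.59.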

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

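The measures below were picked by a fixed test for a lone far value among the 4 wild-type arrays, and no test here was chosen after the result was seen. Of 63 measures tested, 3 were picked, and chance picks about 1 in 20 where no value is clipped at the floor. The score of the hippocampus and dentate gyrus list was 0.256 on wild-type array 2, while the other wild-type arrays lay between 0.029 and 0.0487. Esm1 had a log2 intensity of 4.09 on wild-type array 1 and lay at the floor of 4 on the other wild-type arrays. Equal clipped values on all other arrays force such a pick. Dnase1l2 had a log2 intensity of 4.69 on wild-type array 4 and 4.00 to 4.09 on the others. Some of those were clipped at the floor, so the chance rate does not hold there either.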

How the results depend on the processing

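The floor of 32, log2 of the value plus 16, both renormalizations, the filter above the floor on all 7 arrays, the residual component, the set without wild-type arrays 2 and 3 and the exact test of list scores were chosen after the data had been seen. In 19 of the 21 alternatives 0 probes passed. Array weights gave 28 and the residual component 273. Lists called numbered 3 above the floor on all 7 arrays, 0 with array weights, 2 with the residual component, 2 without wild-type arrays 2 and 3, 3 with the mean over probes, 3 with all probes, and 0 with an estimated correlation, with fry and with the exact test of list scores. Leaving out each array in turn gave 1 to 3. List members adjusted over the list alone numbered 1 without a filter, 52 with array weights, 48 with the residual component, 8 without wild-type arrays 2 and 3, and 2 to 8 leaving out each array in turn. Pde4dip at ILMN_3064283 kept its direction in 18 of 18 alternatives, from -0.77 to -0.63, and passed with array weights (-0.68) and the residual component (-0.71). The residual component is drawn from the same fit, so it leaves the difference unchanged and lowers only its error. The weights rest mostly on wild-type array 1, at 6.71 against 0.104 to 0.855 for the other wild-type arrays. Neither pass is evidence beyond the main fit. The second Pde4dip probe turned sign under cyclic loess (-0.0088), and leaving out each array in turn moved it from -0.10 to 0.16. Of 351 values of the 20 named genes, 0 turned sign and 21 passed, 11 genes with array weights among them. The groups were fully separated at ILMN_3064283 and at the named probes. Leaving out arrays, array weights, another floor or another variance model could therefore not turn a sign there. At a floor of 32 the difference was more than 1.5 times smaller for 8 of 17 genes (Traip 0.035, Hes6 -0.074, Dnase1l2 0.13, Acadl 0.18, Gabpb1 0.19, Rrp1b -0.22, Folr1 -0.52 and S100a9 0.70), and with log2 of the value plus 16 for 5 of 20. Both settings change the differences of dim probes by construction, since they alter the log2 values of low intensities. A probe at the floor on all arrays has no value at a floor of 32.

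The deviations of same-numbered arrays of the 2 groups correlated at 0.080, -0.13 and -0.037, and no array correlated best with its own number. These values gave no sign that the numbers pair the samples. Deviations from the means of so few arrays cannot exclude a pairing. With the replicate number as a block, 0 probes and 1 list passed, the list members numbered 24, and the second Pde4dip probe stood at -0.013.

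The planned changes of background offset, 75th-percentile scaling, quantile normalization of unsubtracted signals and detection p filter were not run, because they needed the table that was not used here. No slide was given, so no slide block was run.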

Other observations

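The tests of the Pde4dip probes, of the chromosome windows, of a shift shared by ribosomal probes, made with the estimated correlation that had been set beforehand, and of the probe counts without weights, and the residual component itself, were chosen after the result was seen, and the genes in the next paragraph were chosen after their values were seen.

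Some pituitary and blood transcripts varied from mouse to mouse, Gh and Prl within both groups. Chgb, also in the pituitary list, had a log2 SD of 0.46 in wild type and 0.046 in knockout. Growth hormone (Gh) read 1275 on wild-type array 4, 351 and 304 on wild-type arrays 1 and 2, and 157 and 87.1 on knockout arrays 1 and 3, while on wild-type array 3 and knockout array 2 it lay under the floor. Prolactin (Prl) read 705 on wild-type array 4 and was likewise under the floor on wild-type array 3 and knockout array 2. Alas2, the haem synthesis enzyme of red cell precursors, read 1045 on wild-type array 2 and 437 on wild-type array 3, against 149 to 252 on the other 5 arrays. The alpha-globin gene Hba-a1 read 26435 and 17439 on the same 2 arrays and 8622 to 13081 on the others. Vasopressin (Avp) and oxytocin (Oxt) were lowest on wild-type array 2, where Avp lay under the floor and Oxt read 34.4, against 93.5 to 254 for Oxt elsewhere. S100a8 and S100a9, which together form the neutrophil protein calprotectin, were highest on the same 2 knockout arrays. S100a8 read 275 on knockout array 1 and 199 on knockout array 3, and 101.2 on knockout array 2, where the wild-type arrays lay between 87.6 and 101.1.

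With array weights, 28 probes passed, and among them were Slc17a7, the vesicular glutamate transporter, at -0.75 (SE 0.10), the zinc transporter gene Slc30a3 at -0.81 (SE 0.13), the nuclear envelope gene Sun1 at 0.60 (SE 0.09) and the transcription factor gene Stat4 at 0.66 (SE 0.10). Chance was not excluded for this count, since 9 of the 35 splits of the arrays gave as many probes and the highest other split gave 1617. For the residual component, 8 of 35 splits gave as many as the real 273, and the highest other gave 3101. The count of 0 without either decides nothing, since each of the 35 splits gives at least 0, and the highest other gave 1. For the 539 probes at an unadjusted p under 0.05, 8 of 35 splits gave as many, and the split of wild-type arrays 1, 2 and 3 from the rest gave 2631, which points to a structure among the arrays. For the 1 list called, 24 of 35 splits gave as many, and the highest other gave 5.

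The lower reading of Pde4dip at ILMN_3064283 was weighed against 3 explanations. The 2 arrays that stand apart do not account for it, since the difference without them was -0.66. A like decrease of all Pde4dip transcripts is argued against by the ratio of ILMN_3064283 to ILMN_2751354 within each array, which separated the groups. The 95% interval of ILMN_2751354 began at -0.453, above -0.71, but the interval around -0.71 itself, from -1.04 to -0.38, overlaps it. The third probe, near the floor, cannot decide, since its interval of -1.04 to 0.35 holds -0.71. The sequence probed by ILMN_3064283 is not missing from the knockout transcripts, unless the probe also binds other RNA, since the lowest knockout intensity was 1233. What stays open, as a hypothesis found and tested on the same data, is that the knockout may lower some Pde4dip transcripts and not others, and the probe positions and cross-binding were not analysed here.

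The top genes lay close together on some chromosomes. Some genes named from a dimmer probe, such as Grwd1 and Rbbp5, are not among these top genes, while Nosip and Ramp3 are. The reason is that each gene was ranked by its probe of highest mean signal. Of the 100 genes with the smallest p by this rule, 17 lay on chromosome 7, where 7.71 are expected. Chromosome 9 held 12 where 6.01 are expected, and chromosome 17 held 9 where 4.98 are expected. Chromosome 3, which carries Pde4dip, held 10 where 4.91 are expected. These 10 include Pde4dip itself and S100a8 and S100a9, which lie side by side. Chromosome 5 held 0 where 6.61 are expected. The counts per chromosome were not compared with the other splits. On chromosome 9, 6 of the 100 genes fell in 1 window of 31 measured neighbours, a count that 10 of 10000 random placements reached. They were Trf, Mrpl3, Glyctk, Rpl29, Abhd14b and 6430571L13Rik, with Mrpl3 at 0.45 at the probe used and -0.58 at its other probe. Chance was not excluded, since 3 of 35 splits gave a window as full and the highest other held 7. With array weights the fullest windows lay on chromosome 7 instead, among Cd33, Zfp658, Ctu1, Cpt1c, Nosip and Slc17a7. They held 5 genes each, in 7 of 35 splits as many, with 8 in the highest other. The part of the 2 arrays that stand apart stays open. Without them a window of this stretch of chromosome 9 held at most 2 of the 100 genes, against a 95th percentile of 4 for the fullest window in random placements. The lower count does not argue for their part, since the differences went from -0.57 to -0.38 for Trf, 0.45 to 0.38 for Mrpl3, -0.48 to -0.50 for Glyctk, -1.22 to -0.89 for Rpl29, 0.56 to 0.53 for Abhd14b and -1.15 to -1.16 for 6430571L13Rik. The fullest windows were then on chromosome 7 with 7 genes each, and 1 of them held Cd33, Ctu1 and Nosip. They overlap the stretch found with array weights. Those weights were lowest for wild-type arrays 2 and 3, so the settings are not independent. The 10 splits of the other 5 arrays are too few for a share under 0.05, and the highest other split held 5. The 60 measured genes beside Pde4dip held 1 of the 100 genes where 0.661 are expected, which decides nothing about windows on other chromosomes. A candidate explanation left open is a segment of another strain's genome in the knockout line, in which variants under the probes could move readings both ways, and it was not tested because probe sequences were not analysed here.

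The lower ribosomal list was weighed against chance and a shift from array to array. Chance was not excluded, since 7 of 35 splits gave a p as small as 1.94e-07, and the smallest of the other splits was 1.20e-09. A shift that ribosomal probes share is consistent with the camera p of 0.170 at an estimated correlation of 0.611, and with high scores on wild-type arrays 2 and 3 alone. An effect of the genotype stays open and untested beyond these values.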
